A study of Mus musculus with 8 samples.

How the data were processed

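RNA from 4 sorted cell groups of Ly6a-GFP transgenic mouse embryos was measured on 8 arrays, 2 per group. Per the labels' protocols, the RNA of each group was split into 2 fractions and amplified with an RNA-Seq amplification kit, and 50 ng were labelled with Cy3 for 1-colour Agilent expression arrays. Per the file headers, the arrays were read with Agilent Feature Extraction 10.10.1.1, and the deposited intensity values include each spot's mean signal, its local background and a processed signal that the scanner software had already background-corrected. The authors also deposited a table of normalized intensity values; what normalization was used is not given in the sources used here. Set against the scanner files, that table was linear, its rows followed the running order of the spots (r of log2 values from 0.997 to 1.000 on the 8 arrays) and each column had a median of 198, so scale and centring are known; it was used only as an alternative. Replicate 1 of all groups lay on 1 slide and replicate 2 on another, so slide is a batch that holds every group, and array position cannot be told apart from group.

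For each array, log2 of the processed signal was taken and the array's 75th percentile over non-control probes subtracted. The 75th percentiles ran from 708 to 1477 in signal units, no probe was saturated, and the share of probes well above background ran from 54.6% to 63.7%. Spots flagged as outliers were left out, which removed 10 probes, and spots of the same probe were averaged, giving 39429 probes from 43020 non-control spots. Probe names were updated through their RefSeq accessions in an annotation table of another mouse assembly, used for names alone: 26055 probes matched by accession, 3195 carried a name that is a current symbol and 10179 kept the name in the file. Each gene was represented by its brightest probe, and only probes well above background on both arrays of at least 1 group were tested, which left 19543 genes. Among named genes with several probes, 3 of 26 in hematopoietic cluster cells by GFP, 4 of 25 in endothelial cells by GFP, 4 of 23 and 0 of 23 between the classes among GFP+ and GFP- cells, and 5 of 27 in the interaction had another probe of opposite sign. Probe coordinates are those of the array files, on mouse build mm9.

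Groups were compared with limma 3.58.1 in R 4.3.3, and files were read with the data.table package (version 1.17.8). There was a single fit over the 8 arrays with a mean for each group, 4 residual degrees of freedom and moderated variances. Tests were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The fit gave 5 contrasts: GFP+ against GFP- in each cell class, hematopoietic cluster cells against endothelial cells at each GFP state, and the interaction. Errors beside fold changes are standard errors of that fit. A gene that was not well above background on either array of a group has only a bound there: the bright group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal. Gene lists, 26 of them with at least 5 measured members, were written before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and contrasts; camera with an estimated correlation was an alternative. Limma's fry, which asks whether a list's genes move one way on balance, passed 22, 25, 25, 20 and 20 of the 26 lists in the 5 contrasts. Before the data were examined the following rule fixed the genes named: the 10 largest called changes each way among genes with a symbol (no clone, Riken or Gm name), well above background on both arrays of both groups (all 4 groups for the interaction) and changed alike on both slides, the 5 largest bounds each way, the sort and sex-linked genes, and up to 4 members of each list that passed or concerned the study's subject, with all members where 5 or fewer passed. The text names a part of these 358 genes. Named are the 5 largest changes each way (3 positive and 2 negative for the interaction). At least the 3 largest bounds each way and examples from the lists are also given. Changes called the largest are so among genes that met the rule's first condition. A gene that is dim in a group can have a larger fitted value. In 1 case a gene was left out and is not reported here.

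The slide was tested as a block because replicate numbers mark it: the correlation of the replicate differences between groups ran from 0.138 to 0.359 over genes, above 0.1 for every pair of groups, so the numbers pair the arrays. The alternatives were normexp background correction (offset 50), quantile normalization, the authors' table, no filter or a stricter filter on dim probes, the mean of a gene's probes, the slide as a block, trend and robust moderation, only the compared groups in the fit, a 2-fold threshold, each array left out in turn and the differences within each slide. Normexp set the 1st percentile of the second GFP- endothelial array at 685, against 56.6 to 75.3 on the others; 2 of its spots lay below their local background, the lowest at a difference of -32157. Normexp with a maximum likelihood estimate, and normexp without spots below their local background, were added after seeing the data. The method was tested on simulated data for 19543 genes, with each gene's mean over the 8 arrays and its residual spread in the fit of all groups. Genes were changed in GFP+ hematopoietic cluster cells and tested against GFP- ones. The fit recovered 47.8% of 67 genes changed by 1.5-fold, 80.6% of 67 changed by 2-fold and 86.4% of 66 changed by 4-fold. There were 8 false calls among 19343 unchanged genes. Noise was independent between genes and fewer genes were changed than were called in the real contrast, so these rates may differ there. Among simulated lists of 40 genes, in GFP+ against GFP- hematopoietic cluster cells, limma's camera found the shifted one. Its unadjusted p-value for an unshifted one was also below 0.05, at 0.0389, so a list call near the threshold is weak evidence.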

Results

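Gene expression was measured in cells sorted from the arteries of mouse embryos at E10.5, when the first hematopoietic stem and progenitor cells arise from the vessel wall. The embryos carried a transgene in which the promoter of Ly6a, the gene for the stem cell antigen Sca-1, drives green fluorescent protein (GFP). The aorta-gonad-mesonephros region and the umbilical and vitelline arteries of 100 embryos were pooled. Hematopoietic cluster cells, the round cells that bud from the arterial wall, carried CD31, VE-cadherin, ESAM and Kit, and endothelial cells carried the same markers without Kit. Each class was divided by GFP, which gave 30000 GFP+ and 130000 GFP- hematopoietic cluster cells and 70000 GFP+ and 300000 GFP- endothelial cells. The RNA of each group was split into 2 fractions, amplified and hybridised to 1-colour expression arrays, so 4 groups had 2 arrays each. The pairs come from divided RNA of pooled embryos, so each p-value of a single gene measures the technical spread between these arrays. The p-values of gene lists, from limma's camera, set a list's genes against all other genes at a preset or estimated correlation. A very small list p-value is therefore no measure of precision between arrays. No p-value here measures variation between pools or sorts, and n counts arrays. Between 54.6% and 63.7% of probes were well above background on an array, and the number of arrays limits the precision.

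The sort markers were read first, as a check of the labels; the gates selected on them, so their differences are no finding. Ly6a (probe on chromosome 15, 74825553 to 74825612, mm9) was read as a mean log2 level relative to each array's 75th percentile. It was -0.53 ± 0.060 (SD, n = 2 arrays of divided RNA) in GFP+ hematopoietic cluster cells and -3.91 ± 0.057 in GFP- ones. In endothelial cells it was 0.39 ± 0.038 in the GFP+ group and -3.67 ± 0.39 in the GFP- group. Kit (chromosome 5, 76052394 to 76052453) was higher in hematopoietic cluster cells than in endothelial cells. The difference was 1.55 ± 0.050 (log2 fold change ± SE, n = 2 against 2 arrays of divided RNA) among GFP+ and 0.64 ± 0.050 among GFP- cells. The mean Kit level was 2.87 in GFP+ cluster cells and 1.32 in GFP+ endothelial cells. Endothelial cells sorted without Kit thus still had Kit RNA above the arrays' 75th percentile. Within hematopoietic cluster cells Kit was higher in the GFP+ group, by 0.89 ± 0.050, adjusted p = 0.000165. Among endothelial cells the Kit log2 difference was -0.014, which did not pass (adjusted p = 0.826). Cdh5, which encodes VE-cadherin, was lower in GFP+ than in GFP- hematopoietic cluster cells (-0.44) and endothelial cells (-0.26, but 0.0021 with quantile normalization), and Pecam1, which encodes CD31, was lower in GFP+ hematopoietic cluster cells than in GFP+ endothelial cells (-0.96). The labels give the sex as male; Xist, Ddx3y and Eif2s3y, transcribed from the inactive X and from the Y chromosome, were all well above background on all 8 arrays of these pooled embryos.

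**Figure D1:**
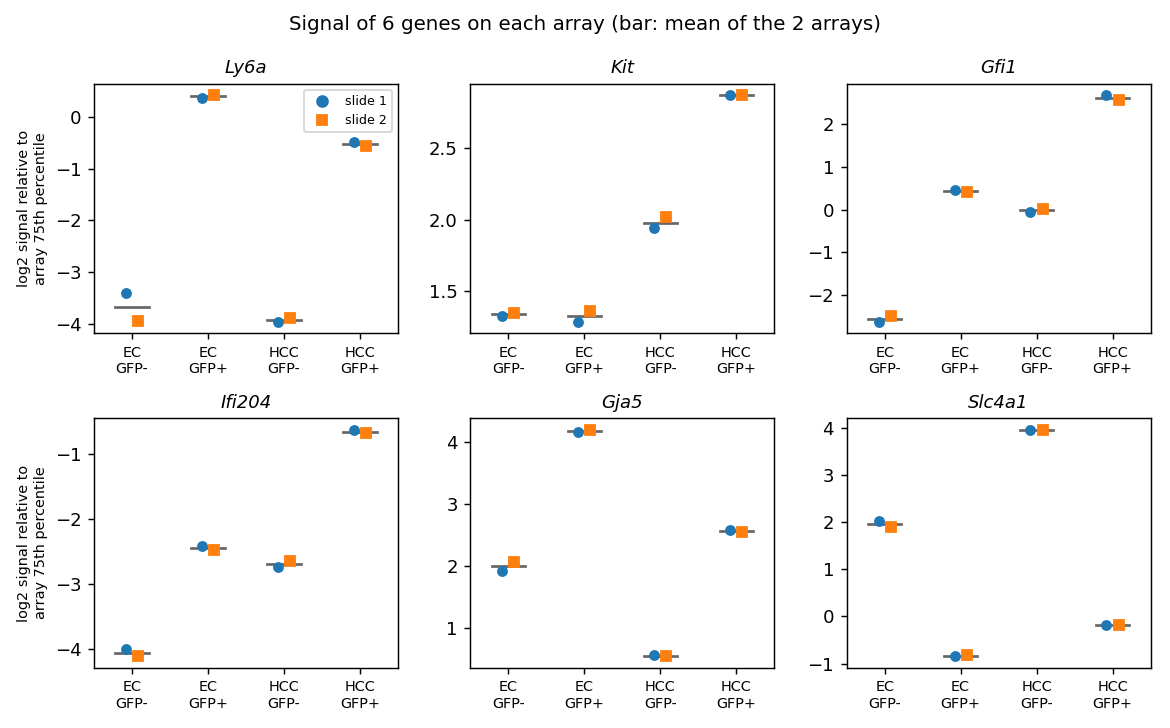
Signal of 6 genes on each of the 8 arrays, as log2 signal relative to the array's 75th percentile (vertical axis), by sorted group (horizontal axis; EC, endothelial cells; HCC, hematopoietic cluster cells). Circles are slide 1, squares slide 2 and bars the mean of the 2 arrays. Ly6a, Gfi1 and Ifi204 lay higher in both GFP+ groups than in their GFP- counterparts, and Slc4a1 lay lower.

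The first comparison set GFP+ against GFP- hematopoietic cluster cells and asks which genes mark the cluster cells in which the stem cell reporter is active. In GFP+ cluster cells, genes of blood cells in general, of macrophages and of the interferon response were higher, and genes of red cell precursors were lower. The largest rises after Ly6a itself were in Wfdc17 (2.71 ± 0.29), Ptpn22 (2.63 ± 0.19), Gfi1 (2.63 ± 0.070, adjusted p = 2.41e-05) and Timd4 (2.61 ± 0.19). Ptpn22 encodes a phosphatase that restrains antigen receptor signalling, and Timd4 a phosphatidylserine receptor of resident macrophages. Gfi1 (chromosome 5, 108145719 to 108145778) encodes a transcriptional repressor that acts within the endothelial to hematopoietic transition. The largest falls were in the erythroid genes Rhd (-4.16 ± 0.060, adjusted p = 5.84e-06), Slc4a1 (-4.15 ± 0.057), the anion exchanger of the red cell membrane, Alas2 (-4.01), the erythroid enzyme of heme synthesis, and Kel (-3.98), and in the amino acid transporter Slc38a5 (-3.99). Some genes were measured only in 1 of the groups and have a bound: Cd274, which encodes PD-L1, was at least 4.75-fold higher, Spic, a transcription factor of red pulp macrophages, at least 4.6-fold and the macrophage protein gene Cd5l at least 4.51-fold higher in GFP+ cells. The water channel gene Aqp3 was at least 24.6-fold lower, Ccdc92b at least 11.4-fold and Lmx1a at least 11.1-fold lower.

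Of 33 measured erythroid genes, 0 rose, 28 fell and 5 did not pass (31 called when adjusted over the list alone); the median log2 fold change was -2.70 (adjusted p = 1.65e-20, limma's camera with Benjamini-Hochberg adjustment). Among 64 measured interferon-response genes, 47 rose and 15 did not pass, with a median of 0.73 (adjusted p = 9.7e-23; 54 called adjusted over the list alone). They included the DNA sensor family member Ifi204 (2.03), the oligoadenylate synthetases Oas1a (1.93, 2.65 by its other probe) and Oas2 (at least 3.4-fold) and Ifi203 (at least 2.73-fold); the 2 that fell were Cmpk2 (-0.86, -0.37 by its other probe) and Rsad2 (-0.57). The myeloid and macrophage list moved with them: 31 of 37 genes rose, 1 fell, which was Csf3r (-0.21), and 5 did not pass (median 1.63, adjusted p = 8.13e-23; 34 adjusted over the list alone), with Lyz2 (2.44) and the signalling adaptor Tyrobp (2.33) among those that rose. Genes shared by most blood cells rose in 33 of 37 cases, such as Spn, which encodes CD43 (2.11), and the phosphatase gene Ptpn6 (1.97); 1 fell, Ncf4 (-0.59), and 3 did not pass. Their median was 1.36 (adjusted p = 4.94e-26; 34 adjusted over the list alone). The tumor necrosis factor, NF-kB and Toll-like receptor list held 22 genes that rose, 2 that fell, Nfkb2 (-0.28) and Relb (-0.47), and 23 that did not pass, of 47 (median 0.20, adjusted p = 9.36e-06; 31 adjusted over the list alone); Il1b was at least 1.94-fold and Ptgs2 at least 1.82-fold higher. Interferon receptors and signal transducers did not pass as a list (4 rose and 4 fell of 19; median 0.046, adjusted p = 0.288; 9 adjusted over the list alone): the DNA sensor gene Cgas (1.19), Irf5 (1.92, not well above background on every array), Ifnar2 (0.31) and Ifngr1 (0.27) rose, and Ifnar1 (-0.30, 0.060 by another probe), Ifngr2 (-0.34), Sting1 (-0.31) and Tyk2 (-0.20) fell.

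Of 40 hematopoietic regulators 18 rose, 9 fell and 13 did not pass (median 0.16, adjusted p = 0.0018, but adjusted p = 0.115 with an estimated correlation; 30 adjusted over the list alone); Hlf (2.41), a transcription factor of hematopoietic stem cells, and Runx1 (1.96; chromosome 16, 92605785 to 92605844), required for blood formation from endothelium, rose. Among 35 stem cell genes 17 rose, 9 fell and 9 did not pass (median 0.36, adjusted p = 6.69e-05, but adjusted p = 0.082 with an estimated correlation; 27 adjusted over the list alone), with Angpt1 (1.84) and Gcnt2 (1.94) higher. Of 28 cytokine receptors 15 rose, 6 fell and 7 did not pass (median 0.41, adjusted p = 0.000346; 21 adjusted over the list alone), among them Il6ra (1.94) and Csf1r (1.83, 0.94 by another probe), the receptor for macrophage colony-stimulating factor. The arterial and Notch list did not pass (adjusted p = 0.265; 10 rose, 11 fell of 32; 26 adjusted over the list alone), and its median of -0.056 and mean of 0.16 differed in sign, the test pointing up. The gap junction gene Gja5 (2.01 by its brightest probe, 0.95 by the other) and Bmx (1.501) rose and Igfbp3 (-1.17) fell. Genes of mesenchyme and smooth muscle fell in 20 of 31 cases, such as Col3a1 (-1.30), and rose in 4, Acta2 (0.22), Dlk1 (0.19), Fbn1 (0.75) and Gata4 (0.70), with 7 not passing. Their median was -0.64 (adjusted p = 0.000187; 24 adjusted over the list alone). Of 21 megakaryocyte and platelet genes 11 rose, such as Itgb3 (1.61), 4 fell, Clec1b (-0.65), F2r (-0.27), Gata1 (-1.63) and Tubb1 (measured in the GFP- group alone), and 6 did not pass. Their median was 0.29 (adjusted p = 0.000187; 15 adjusted over the list alone).

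Over all genes, limma called 6395 of 19543 at a Benjamini-Hochberg adjusted p under 0.05, 2306 higher and 4089 lower in GFP+ cluster cells, and 1052 of them by at least 2-fold, 585 higher and 467 lower. The share called higher was 36.1%, against 45.7% with quantile normalization and 44.3% in the authors' normalized table. The count fell to 3675 without the first array of the GFP- group and 4070 without the second, to 3792 with no filter on dim probes and, with the planned normexp background correction, to 127, where 2 spots of 1 endothelial array set its floor. Of the 26 lists tested, 16 passed, and 8 did with an estimated correlation.

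The second comparison set GFP+ against GFP- endothelial cells and asks which genes go with reporter activity in endothelial cells sorted without Kit. GFP+ endothelial cells had higher arterial, interferon-response and macrophage genes and lower erythroid genes. After Ly6a, the largest rises were in Cytl1 (3.03 ± 0.090), Gcg (2.99 ± 0.084), which encodes proglucagon, Gfi1 (2.98 ± 0.070, adjusted p = 3.23e-05) and Htra1 (2.90 ± 0.050), a secreted protease. The largest falls were in Alas2 (-2.80 ± 0.076), Slc4a1 (-2.80 ± 0.057) and Rhd (-2.78 ± 0.060), in the keratin-associated protein gene Krtap19-4 (-2.63) and in the globin gene Hbb-bt (-2.52). As bounds, Syt15 was at least 8.48-fold, Pnoc at least 7.41-fold and the phosphodiesterase gene Pde3a at least 5.88-fold higher by its brightest probe (log2 fold change 1.54 by the other), and Mst1 at least 5.81-fold, Fgf14 at least 4.57-fold and Ank1, the red cell ankyrin, at least 4.34-fold lower in GFP+ endothelial cells.

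The median of all genes lay at -0.13 here, against -0.025 with quantile normalization, so list medians in this comparison are given relative to it. Counts of genes that rose or fell and values of single genes are as fitted. Where changes are small, those counts therefore depend in part on the scaling. Of 64 interferon-response genes 50 rose, 13 did not pass and 1 fell, which was Cmpk2 (-0.19, -0.41 by its other probe). The relative median was 0.75 (adjusted p = 1.13e-17; 51 adjusted over the list alone), with the guanylate-binding protein gene Gbp4 (1.82), Oasl2 (1.64) and Ifi204 (1.61) as examples and Ifi44 (chromosome 3, 151394035 to 151394094) at least 2.48-fold higher. Beside them, 28 of 37 myeloid and macrophage genes rose, such as Tyrobp (1.90) and Adgre1 (1.77). In this list 2 fell, the granule enzyme genes Mpo (-0.52, -0.0035 by its other probe) and Prtn3 (-0.70), and 7 did not pass. Their relative median was 1.11 (adjusted p = 8.15e-12; 32 adjusted over the list alone). The arterial and Notch list rose in 18 of 32 genes, among them Gja5 (2.18, 0.62 by its other probe; chromosome 3, 96857349 to 96857408), Fbln5 (2.19) and Bmx (1.82); 5 fell, Hes1 (-0.58), Hes5 (-1.04), Igfbp3 (-0.85), Notch1 (-0.34, 0.65 by its other probe) and Unc5b (-0.25), and 9 did not pass. They had a relative median of 0.47 (adjusted p = 1.92e-06; 24 adjusted over the list alone). Erythroid genes fell in 28 of 33 cases and 5 did not pass. Their relative median was -1.40 (adjusted p = 6.58e-11; 29 adjusted over the list alone). The tumor necrosis factor, NF-kB and Toll-like receptor list had 23 genes that rose, 6 that fell and 18 that did not pass (relative median 0.38, adjusted p = 2e-05; 29 adjusted over the list alone), with the chemokine gene Cxcl1 (1.31) and the NF-kB inhibitor gene Tnfaip3 (0.98) higher and Il1b at least 2.26-fold higher. Genes of blood cells rose in 19, fell in 8 and did not pass in 10 of 37 cases (relative median 0.34, adjusted p = 0.000346; 28 adjusted over the list alone), as in Spn (1.92, 1.17 by its other probe) and Cd44 (1.36 by its brightest of 3 probes, -0.16 by another).

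Of 35 stem cell genes 19 rose, 7 fell and 9 did not pass (relative median 0.37, adjusted p = 0.000433, but adjusted p = 0.102 with an estimated correlation; 28 adjusted over the list alone), with Hlf (1.38) and Prdm16 (1.17) higher. Among 35 genes of endothelium in general 17 rose, 7 fell and 11 did not pass (relative median 0.26, adjusted p = 0.000377, but adjusted p = 0.102 with an estimated correlation; 25 adjusted over the list alone); von Willebrand factor, Vwf (2.27), rose and Esm1 (-1.31) fell. The hematopoietic regulators did not pass as a list (16 rose, 12 fell of 40; relative median 0.22, adjusted p = 0.0606; 30 adjusted over the list alone), with Ikzf2 (1.57, 0.51 by its other probe) higher and Etv2 (-1.61), a regulator of early endothelial and blood precursors, lower. Bone morphogenetic protein and transforming growth factor genes rose in 13 of 29 cases, such as Ltbp4 (2.05) and Bmp6 (1.84), 5 fell, Bmp7 (-0.56), Bmpr2 (-0.58), Nog (-1.81, not measured on every array), Tgfb3 (-0.44) and Tgfbi (-0.28), and 11 did not pass. They had a relative median of 0.29 (adjusted p = 0.00352, but adjusted p = 0.226 with an estimated correlation; 20 adjusted over the list alone). Megakaryocyte and platelet genes fell in 13 of 21 cases, such as Pf4 (-1.09), rose in 2, F2r (0.46) and Gp1ba (0.30), and did not pass in 6. Their relative median was -0.60 (adjusted p = 0.0247, but adjusted p = 0.117 with an estimated correlation and adjusted p = 0.0549 with the slide as a block; 16 adjusted over the list alone). Mitochondrial respiratory chain genes fell in 25 of 33 cases, such as Cycs (-0.70), and 8 did not pass. They had a relative median of -0.19 (adjusted p = 0.000346, but adjusted p = 0.372 with an estimated correlation; 29 adjusted over the list alone). Ribosome and nucleolus genes fell in 23 of 36 cases, such as Rps19 (-0.56), rose in 2, Myc (0.53) and Polr1b (0.50), and did not pass in 11 (relative median -0.15, adjusted p = 0.0198, but adjusted p = 0.419 with an estimated correlation; 27 adjusted over the list alone); the list's median as fitted turned to 0.011 with quantile normalization.

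Limma called 10065 of 19543 genes, 3547 higher and 6518 lower in GFP+ endothelial cells, and 1403 by at least 2-fold, 480 higher and 923 lower. The share called higher was 35.2%, but 50.7% of 8411 with quantile normalization and 48.5% of 8501 in the authors' normalized table, so the balance of directions depends on the scaling. With the planned normexp correction 100 genes were called, and Gp1ba, Hlf, Ifi204, Ifi44, Ikzf2, Il1b, Pde3a and the medians of the respiratory chain and ribosome lists turned direction. Of the 26 lists, 15 passed, and 6 did with an estimated correlation.

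**Figure D2:**
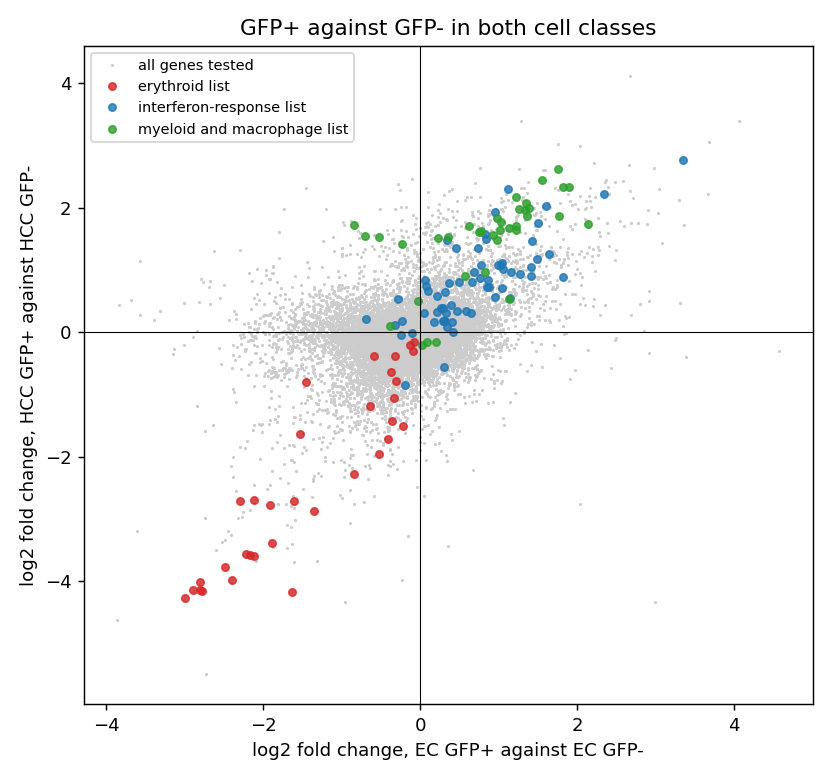
Log2 fold change of GFP+ against GFP- in endothelial cells (EC, horizontal axis) and in hematopoietic cluster cells (HCC, vertical axis) for the 19543 genes tested. Grey points are all genes and coloured points the erythroid, interferon-response and myeloid and macrophage lists. Erythroid genes lay below 0 on both axes, with medians of -1.53 and -2.70.

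The GFP contrasts of both classes share no array, so they can be set against each other. Across genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.414 and Spearman's rho = 0.307. Of the genes called in both, 1265 were higher in both GFP+ groups, where independent lists would share 419, and 2152 were lower in both (1364 by independence). Opposite directions were seen for 730 genes (1511 by independence), and without the erythroid list r was 0.402. Both contrasts used the same variance of each gene, which alone can raise the number called in both, whatever the direction.

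The interaction tests whether the GFP contrast itself differs between the cell classes, and a positive value means a larger log2 change in hematopoietic cluster cells. Blood cell and megakaryocyte genes had the more positive GFP contrast in cluster cells, and erythroid, endothelial and matrix genes the more positive one in endothelial cells. Of 37 blood cell genes 32 had a positive interaction and 5 did not pass (median 0.93, adjusted p = 5.74e-16; 33 adjusted over the list alone), such as Plek (2.01) and the tyrosine kinase gene Btk (1.97, 1.29 by its other probe). Megakaryocyte and platelet genes were positive in 14 of 21 cases, among them Rgs18 (2.64), Gp9 (2.22) and Pf4 (1.68), negative in 1, F2r (-0.73), and did not pass in 6. Their median was 1.25 (adjusted p = 1.94e-07; 16 adjusted over the list alone). The myeloid and macrophage list had 21 positive, 2 negative, Cd93 (-0.36) and Mrc1 (-0.60), and 14 not passing of 37 (median 0.61, adjusted p = 1.93e-06, but adjusted p = 0.0506 with an estimated correlation; 28 adjusted over the list alone), with Mpo (2.05) and Prtn3 (2.24) among the positive. Erythroid genes were negative in 24 of 33 cases, such as Kel (-1.59), positive in 1, the carbonic anhydrase gene Car2 (0.66), and did not pass in 8. Their median was -1.21 (adjusted p = 1.37e-12; 27 adjusted over the list alone). Endothelial genes were negative in 23 of 35 cases with 12 not passing (median -0.39, adjusted p = 1.2e-09; 26 adjusted over the list alone), such as Tek (-0.92), the angiopoietin receptor, and Emcn (-0.82). Arterial and Notch genes were negative in 19, positive in 4, Cd44 (0.50, 1.42 by another probe), Hes5 (0.75), Notch1 (0.46, -0.96 by its other probe) and Slc45a4 (0.61), and not passing in 9 of 32 cases (median -0.38, adjusted p = 4.47e-05, but adjusted p = 0.0653 with an estimated correlation; 24 adjusted over the list alone), with endothelin, Edn1 (-1.36), among the negative. For the interferon-response list no difference was shown: 12 genes were positive, 8 negative and 44 of 64 did not pass (median 0.053, adjusted p = 0.814; 25 adjusted over the list alone), with Oas1a at 0.97 and Gbp4 at -0.93. The tumor necrosis factor list did not pass either (adjusted p = 0.724, median -0.012). Where a group was not well above background the sign of the interaction can be open. It was measured for 31 of the 32 positive blood cell genes and 12 of the 14 positive megakaryocyte genes. It was also measured for 18 of the 21 positive myeloid genes and 22 of the 24 negative erythroid genes. The largest interactions of single genes are given among genes well above background in all 4 groups. Positive ones were Krtap19-4 (3.93 ± 0.49), Spint2 (3.25 ± 0.39, 0.22 by its other probe) and Cyp17a1 (3.13 ± 0.26), a steroid hydroxylase gene. Negative ones were Slc38a5 (-3.75 ± 0.066) and the chloride channel gene Ano1 (-2.16 ± 0.080). Limma called 6080 genes, 3061 positive and 3019 negative (50.3% positive, but 43.0% with quantile normalization and 44.2% in the authors' table), and 14 of 26 lists passed (6 with an estimated correlation). The count was 3580 without the first array of GFP- hematopoietic cluster cells, 3879 and 3902 without either array of GFP- endothelial cells, 2743 with no filter on dim probes and 1 with the planned normexp correction.

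**Figure D3:**
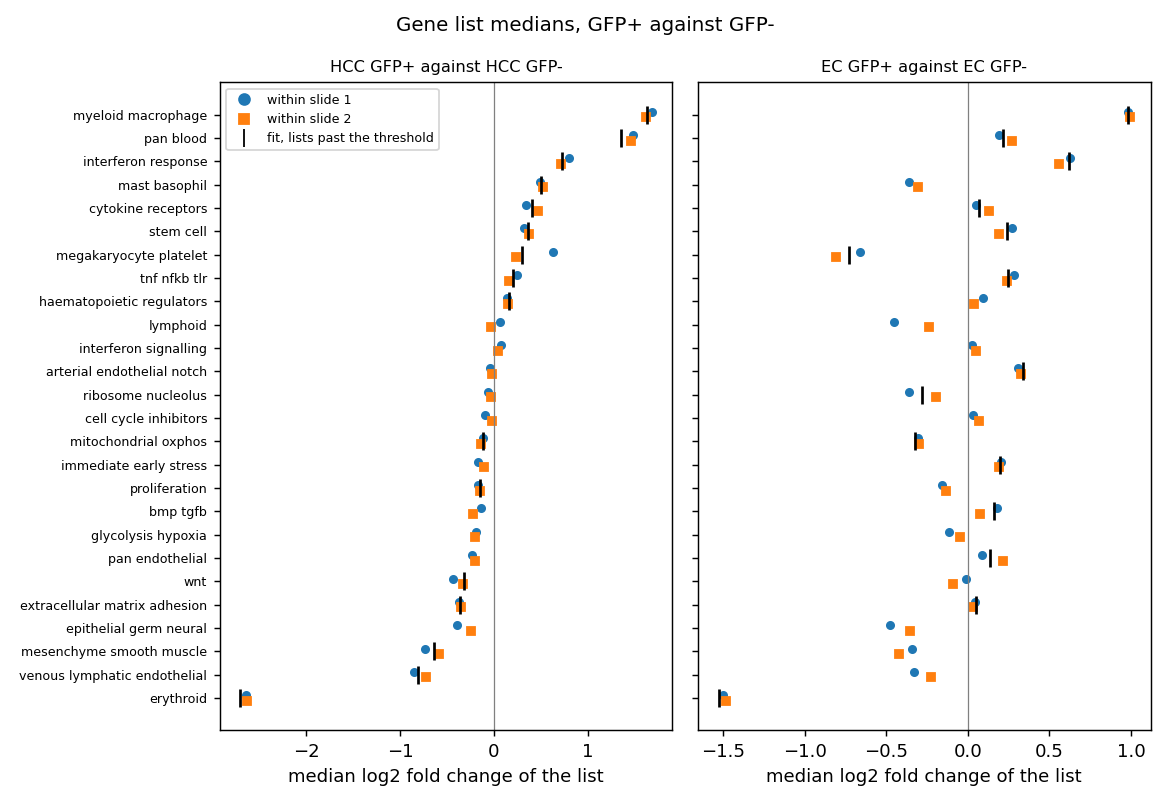
Median log2 fold change of each of the 26 gene lists, GFP+ against GFP-, in hematopoietic cluster cells (HCC, left) and endothelial cells (EC, right). Circles and squares are the difference within slide 1 and slide 2, and a black tick is the fitted median of a list that passed its test. The erythroid list lay lowest in both panels, and the interferon-response medians were 0.73 and 0.62.

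The third comparison set hematopoietic cluster cells against endothelial cells among GFP+ cells, which asks what separates the clusters from the reporter-active vessel wall. GFP+ cluster cells had higher blood and myeloid genes and lower endothelial, arterial and matrix genes. The largest rises were in the granule enzyme gene Mpo (4.92 ± 0.068), Myb (4.49 ± 0.062, adjusted p = 4.94e-06), a transcription factor of definitive blood progenitors, Hlf (4.09 ± 0.21), Tuba8 (4.06) and Wdfy4 (4.03). The largest falls were in Mal (-2.17 ± 0.11), Tmem100 (-2.13 ± 0.047), Alb, which encodes albumin (-1.98), Htra1 (-1.89) and Slc38a5 (-1.89). As bounds, Pstpip1 was at least 21.3-fold, Tespa1 at least 20.8-fold and Rab44 at least 13.6-fold higher in cluster cells, and Gcg at least 11.5-fold, the neutrophil gene S100a9 at least 8.56-fold and Cstdc5 at least 7.3-fold lower.

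Of 37 blood cell genes 36 rose and 1 did not pass (median 1.99, adjusted p = 1.54e-19; 36 adjusted over the list alone), such as Rac2 (3.75) and Coro1a (3.44). Myeloid and macrophage genes rose in 32 of 37 cases, 1 fell, Cd93 (-0.55), and 4 did not pass. Their median was 1.78 (adjusted p = 4.39e-13; 33 adjusted over the list alone). Genes of endothelium in general fell in 29 of 35 cases and 6 did not pass (median -0.58, adjusted p = 6.58e-11; 30 adjusted over the list alone), among them Emcn (-1.02) and the nitric oxide synthase gene Nos3 (-1.02). The arterial and Notch list fell in 27 of 32 genes, such as Fbln5 (-1.66) and Hey1 (-1.56), rose in 3, Cd44 (1.38, 2.43 by another probe), Notch1 (0.43, -1.05 by its other probe) and Slc45a4 (0.34), and did not pass in 2. Their median was -0.82 (adjusted p = 3.37e-09; 31 adjusted over the list alone). Matrix and adhesion genes fell in 29 of 36 cases, as in Col4a2 (-1.13), rose in 1, Itgb5 (0.30), and did not pass in 6. Their median was -0.68 (adjusted p = 5.17e-11; 30 adjusted over the list alone). Mesenchyme genes fell in 22 of 31 cases, such as Lum (-1.15), rose in 1, Dlk1 (0.42), and did not pass in 8. Their median was -0.63 (adjusted p = 1.14e-07; 24 adjusted over the list alone). Of 40 hematopoietic regulators 25 rose, 9 fell and 6 did not pass (median 0.54, adjusted p = 0.000154, but adjusted p = 0.082 with an estimated correlation; 34 adjusted over the list alone), with Gfi1b at 3.36. Interferon-response genes rose in 31, fell in 14 and did not pass in 19 of 64 cases (median 0.27, adjusted p = 0.0377, but adjusted p = 0.117 with an estimated correlation; 46 adjusted over the list alone), with Ifitm1 (3.55) and the immunoproteasome gene Psmb8 (1.73) higher. The stem cell (adjusted p = 0.567, median 0.056), tumor necrosis factor (adjusted p = 0.34, median 0.073) and erythroid lists (adjusted p = 0.728, median 0.11) did not pass. The megakaryocyte list did not pass (adjusted p = 0.814), its median of -0.33 and mean of 0.46 differing in sign. Limma called 9837 genes, 5105 higher and 4732 lower, and 1931 by at least 2-fold, 1505 higher and 426 lower. The share called higher was 51.9%, but 44.7% with quantile normalization and 45.5% in the authors' table, so which direction holds the majority depends on the scaling. In all, 136 were called with the planned normexp correction. Of the 26 lists 12 passed, and 6 did with an estimated correlation.

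The fourth comparison set hematopoietic cluster cells against endothelial cells among GFP- cells. GFP- cluster cells had higher erythroid, macrophage and blood regulator genes. Of the lists that passed, 8 were higher in these cells and 7 were lower. The arterial, platelet and respiratory chain lists were among the lower ones. The largest rises were in Myb (3.47 ± 0.062, adjusted p = 3.47e-05), Hlf (3.06 ± 0.21), Spn (2.995 ± 0.066, 2.29 by its other probe), Mpo (2.88) and the chemokine gene Ccl9 (2.86). The largest falls were in the platelet genes Ppbp (-2.77 ± 0.066), Pf4 (-2.04 ± 0.057), Treml1 (-1.91) and Gp6 (-1.85) and in thrombospondin, Thbs1 (-1.70). As bounds, Ikzf1, a transcription factor of lymphoid and other blood cells, was at least 9.05-fold, Gpr171 at least 6.21-fold and Tespa1 at least 5.45-fold higher, and S100a9 at least 11-fold, Cstdc5 at least 8.89-fold, Stfa1 at least 8.19-fold and S100a8 (chromosome 3, 90473778 to 90473837) at least 4.49-fold lower.

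Of 33 erythroid genes 29 rose and 4 did not pass (median 0.99, adjusted p = 8.39e-21; 30 adjusted over the list alone), such as Kel (2.36) and Slc4a1 (2.00). Myeloid and macrophage genes rose in 28 of 37 cases and 9 did not pass (median 1.15, adjusted p = 6.32e-18; 32 adjusted over the list alone), with Tyrobp at 1.59. Blood cell genes rose in 24 of 37 cases, 1 fell, Lcp1 (-0.27), and 12 did not pass (median 0.88, adjusted p = 2.01e-16; 33 adjusted over the list alone), with Rac2 at 2.76. Of 40 hematopoietic regulators 24 rose, such as Gfi1 (2.53), 2 fell, Ebf1 (-0.34) and Lmo2 (-0.29), and 14 did not pass. Their median was 0.38 (adjusted p = 4.22e-10; 30 adjusted over the list alone). Arterial and Notch genes fell in 16 of 32 cases, such as Gja5 (-1.44, -0.70 by its other probe) and Gja4 (-1.37), rose in 3, Cd44 (0.88), Dll1 (0.20) and Edn1 (0.38), and did not pass in 13. Their median was -0.37 (adjusted p = 1.6e-05, but adjusted p = 0.0596 with an estimated correlation; 22 adjusted over the list alone). Interferon-response genes rose in 27 of 64 cases, such as Ifitm1 (2.42), fell in 4, B2m (-0.27), Isg15 (-0.66), Socs1 (-0.30) and Xaf1 (-0.68), and did not pass in 33 (median 0.20, adjusted p = 9.25e-05; 35 adjusted over the list alone); this median turned to -0.38 with the planned normexp correction. Megakaryocyte and platelet genes fell in 11 of 21 cases, rose in 4, among them Gata1 (1.17), Nfe2 (1.75) and Selp (at least 2.02-fold), and did not pass in 6. Their median was -0.68 (adjusted p = 0.00143, but adjusted p = 0.0645 with an estimated correlation; 17 adjusted over the list alone). Mitochondrial respiratory chain genes fell in 18 of 33 cases, such as Ndufa4 (-0.46), and 15 did not pass. Their median was -0.22 (adjusted p = 1.14e-07, but adjusted p = 0.226 with an estimated correlation; 20 adjusted over the list alone). Immediate early and stress genes, which also respond to cell dissociation, rose in 13 of 31 cases, such as Fosl2 (0.65) and Fos (0.50), fell in 1, Ccn1 (-0.17), and did not pass in 17. Their median was 0.20 (adjusted p = 8.46e-05; 20 adjusted over the list alone). Limma called 4730 genes, 2308 higher and 2422 lower, and 418 by at least 2-fold, 355 higher and 63 lower. The share called higher was 48.8%, but 53.0% with quantile normalization and 52.5% in the authors' table. The count was 1606 to 2012 without any single array of either GFP- group (1648 and 1606 without the first and second of the cluster cells, 2012 and 1964 of the endothelial cells), 1466 with no filter on dim probes, 2576 with only these groups in the fit and 14 with the planned normexp correction. That correction also turned the direction of B2m, Dll1, Lcp1, Selp, Tespa1 and the respiratory chain median. Of the 26 lists 15 passed, and 8 did with an estimated correlation.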

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

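The tests of a common erythroid source, of macrophages and of the scaling of the arrays were chosen only after the results they bear on were seen, as were the conditions on spread and on signal above background in the neutrophil and keratinocyte tests. The GFP contrast differed between hematopoietic cluster cells and endothelial cells by the interaction test for 14 of 26 lists and 124 of 179 named genes (limma, adjusted p under 0.05), some of them named for a large interaction; over all genes the share was 31.1%. With an estimated correlation 6 of the lists passed: the blood cell, megakaryocyte, erythroid, endothelial, matrix and immediate early lists. The respiratory chain and ribosome medians turned to -0.12 and -0.068 with the planned normexp correction. Lists whose GFP contrast was more positive in hematopoietic cluster cells had interaction medians of 1.25 (megakaryocyte and platelet), 0.93 (blood cell), 0.61 (myeloid and macrophage), 0.21 (respiratory chain) and 0.19 (ribosome). Lists whose GFP contrast was more negative in hematopoietic cluster cells had interaction medians of -1.21 (erythroid), -0.53 (venous and lymphatic), -0.43 (matrix and adhesion), -0.40 (immediate early), -0.39 (endothelial), -0.39 (Wnt), -0.38 (arterial and Notch), -0.34 (bone morphogenetic protein) and -0.16 (mesenchyme). A more positive contrast in cluster cells was found for Krtap19-4 (3.93), Fgf14 (3.30), Spint2 (3.25), Cyp17a1 (3.13), Rgs18 (2.64), Tuba8 (2.36), Prtn3 (2.24), Gp9 (2.22), Mpo (2.05), Plek (2.01), Btk (1.97), Coro1a (1.74), Gfi1b (1.72) and Pf4 (1.68). Cluster cells had the more positive contrast for Itgb3 (1.54), Gcnt2 (1.47), Angpt1 (1.42), Ppbp (1.41), Nfe2 (1.36), Treml1 (1.32), Wdfy4 (1.27), Ifitm1 (1.14), Runx1 (1.08), Hlf (1.04), Myb (1.01), Ccl9 (1.01) and Ptpn6 (1.01). A more positive contrast in cluster cells was found for Rac2 (0.995), Oas1a (0.97), Kit (0.91), Csf1r (0.85), Gp1ba (0.79), Hes5 (0.75), Psmb8 (0.66), Car2 (0.66), Il6ra (0.63), Slc45a4 (0.61), Srgn (0.61), Sfrp2 (0.55), Cgas (0.53) and Cycs (0.51). Cluster cells had the more positive contrast for Cd44 (0.50), Notch1 (0.46), Ifngr1 (0.46), Ikzf2 (0.44), Lmo2 (0.44), Tyrobp (0.42), Ifi204 (0.42), Ndufa4 (0.41), Thbs1 (0.40), Ncf4 (0.38), Rps19 (0.36), Lcp1 (0.31) and Ndufb5 (0.27). A more negative contrast in cluster cells was found for Gcg (-7.33), Slc38a5 (-3.75), Ccdc92b (-3.37), Ano1 (-2.16), Lmx1a (-1.77), Kel (-1.59), Bmp6 (-1.59), Rhd (-1.38), Edn1 (-1.36), Slc4a1 (-1.34), Sfrp1 (-1.32), Fbn1 (-1.30), Mal (-1.25) and Klf4 (-1.24). Cluster cells had the more negative contrast for Alas2 (-1.21), Cytl1 (-1.11), Fbln5 (-1.07), Alb (-1.06) and Gata4 (-1.02). A more negative contrast in cluster cells was found for Htra1 (-0.94), Gbp4 (-0.93), Tek (-0.92), Vwf (-0.91), Tmem100 (-0.89), Rsad2 (-0.86), Hbb-bt (-0.85), Dll1 (-0.83), Emcn (-0.82), Unc5b (-0.82), Col4a2 (-0.77), Ltbp4 (-0.76), Col3a1 (-0.75) and Osmr (-0.74). Cluster cells had the more negative contrast for F2r (-0.73), Tgfbi (-0.70), Fosl2 (-0.68), Ccn1 (-0.68), Cmpk2 (-0.67), Cxcl1 (-0.64), Pecam1 (-0.63), Mki67 (-0.63), Mrc1 (-0.60), Nos3 (-0.56), Myc (-0.54), Tbx1 (-0.53), Fos (-0.52) and Ebf1 (-0.46). A more negative contrast in cluster cells was found for Hey1 (-0.45), Stmn2 (-0.39), Oasl2 (-0.38), Cd93 (-0.36), Gfi1 (-0.35), Ifnar1 (-0.34), Igfbp3 (-0.32), Bmx (-0.32) and Ifngr2 (-0.24). For 14 of the named genes the fit gave a value whose direction was not measured, because neither group of 1 class was well above background on both arrays or the bounds leave the direction open: Pstpip1 (2.50), Ptpn22 (1.86), Rab44 (1.83), Ikzf1 (1.76), Selp (1.62), Tespa1 (1.62), Gpr171 (1.56), Cd5l (1.44), S100a9 (1.28), Spic (1.25), Gp6 (0.94), Pnoc (-1.15), Syt15 (-1.65) and Ank1 (-2.78). These values come from each gene's brightest probe. Another probe turned the sign for Cmpk2 (0.042), Ifnar1 (0.28), Notch1 (-0.96) and Runx1 (-0.022). Without turning it, another probe lay over 1.5-fold away for Spint2 (0.22), Btk (1.29), Cd44 (1.42), Ikzf2 (1.41) and Lcp1 (1.07), and Ndufb5 stood at 0.12 by its other probe. Some of these genes, Gcg among them, were not well above background in every group, and their fitted values are no measured size.

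Erythroid genes were lower in both GFP+ populations, with medians of -2.70 in hematopoietic cluster cells and -1.53 in endothelial cells; an abundant one, Hbb-y, stood at 8.92 in GFP- and 6.22 in GFP+ cluster cells (log2 relative to the 75th percentile). The scaling of the arrays was argued against, since the medians under quantile normalization were -2.32 and -1.40. A common source, red cells or their RNA in the GFP- gates, would move globins and other erythroid genes alike between the GFP- groups. The medians were 1.56 (12 erythroid-restricted genes) and 0.75 (7 globins), a difference of 0.82 with a 95% bootstrap interval from 0.53 to 1.35. The brightest globins, Hbb-y (0.46), Hbb-bh1 (0.36) and Hba-a2 (0.33), moved less than Hba-x (1.03), Hba-a1 (0.94), Hbb-bt (0.82) and Hbb-b2 (0.75). Whether compression of bright signals lowered the globin median was not tested. The difference of the medians lies between the bounds set for either answer, so the test does not decide on a common source. No outcome of it could tell such a source from erythroid cells that truly belong to the GFP- populations. Those cells could also move both kinds of gene alike. How many mature red cells the gate on CD31, VE-cadherin and ESAM removed was not measured. Fewer cells with erythroid potential among GFP+ cells, a difference of the sorted populations themselves, stays open and untested.

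Interferon-response genes were higher in both GFP+ populations, and macrophage genes rose with them, Lyz2 from -3.58 to -1.14 in cluster cells. Scaling was argued against: under quantile normalization the list's medians lay 0.78 and 0.65 above the median of all genes. If macrophages alone supplied both, the rise on the linear scale in cluster cells over that in endothelial cells would be alike for both kinds of gene; its log2 median was 0.59 over 64 interferon-response genes, with the 8 that did not rise in both set highest, and 2.26 for 12 macrophage-restricted genes, a difference of -1.67 (95% bootstrap interval -2.16 to -0.98). This speaks against macrophages as the whole source, while a part of the rise may still come from them. How many macrophages the VE-cadherin gate removed was not measured. Ly6a is itself interferon-inducible, so a reporter that marks cells under interferon signalling is a candidate biological explanation, which was not tested.

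The neutrophil genes S100a8, S100a9 and Stfa1 were higher in the endothelial gates, S100a9 at -1.75 in GFP- endothelial cells. In GFP- cluster cells S100a9 was not well above background, so its fitted level of -7.47 is no measured size. Mature neutrophils would bring their other abundant transcripts, but the higher of the median changes, cluster minus endothelial cells, of the 12 of 18 other neutrophil genes that were measured was 0.30 (95% bootstrap interval -0.21 to 0.51), although Camp (-0.36 among GFP+ and -0.44 among GFP- cells) and Ltf (-0.88 and -0.11) lay on the endothelial side in both. Keratinocytes, which can also express these genes, would bring keratins, but the higher median of the 8 of 14 keratinocyte genes that were measured was 0.55 (0.29 to 1.62). These medians speak against those cells as the main source, with limits. Of the genes measured, 4 neutrophil and 2 keratinocyte genes were not well above background in both endothelial groups, and Csf3r had a high baseline. Cluster cells also had the higher myeloid genes at both GFP states. Genes that neutrophils share with other myeloid cells could thus raise the neutrophil median, which was not tested. Expression by Kit- endothelial cells themselves was not tested.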

How the results depend on the processing

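Normexp by maximum likelihood and normexp without spots below local background were chosen only after the data were seen; all other alternatives were planned. The slide as a block gave 6875, 11140, 10784, 5230 and 7089 genes (GFP contrast in hematopoietic cluster cells, then in endothelial cells, cluster against endothelial cells among GFP+, then GFP- cells, and the interaction; this order holds below) and moved no count by over 1.5 times; it ended the calls of the platelet list in endothelial cells (adjusted p = 0.0549) and the venous list in cluster cells (adjusted p = 0.0503), made calls of the bone morphogenetic protein (adjusted p = 0.0468) and mast cell lists (adjusted p = 0.0413) between the GFP- classes, and changed no other call of a list or of a gene named in the report or the other observations. The planned normexp correction gave 127, 100, 136, 14 and 1 genes and its maximum likelihood form 125, 86, 133, 14 and 1; 2 spots of the second GFP- endothelial array raised that array's floor, and without spots below local background the counts were 4594, 7622, 7117, 2727 and 3764. The planned form also moved the median of all genes to -0.26, -0.18 and 0.20 in endothelial cells by GFP, between the GFP- classes and in the interaction. At 2-fold or more 1052, 1403, 1931, 418 and 1108 genes passed; with no filter on dim probes 3792, 8194, 9069, 1466 and 2743 did, and with only the compared groups 4426, 9196, 7717 and 2576, with more dim genes tested in the first and fewer arrays in the second. An estimated correlation left 8, 6, 6, 8 and 6 of 26 lists. Leaving out 1 array in turn gave 3675 to 5730, 7210 to 10084, 7465 to 9137, 1606 to 4211 and 3580 to 4657 genes, and 15 to 17, 15 to 16, 11 to 13, 16 to 17 and 14 to 15 lists, with the lone array of a group assumed to vary like the others. The arrays that moved a count by over 1.5 times were those of GFP- cluster cells (3675 and 4070 in their GFP contrast, 1648 and 1606 against endothelial cells, 3580 for the first in the interaction) and of GFP- endothelial cells (2012 and 1964 against cluster cells, 3879 and 3902 in the interaction). Directions that turned with the planned normexp, and with its maximum likelihood form as the second value, follow. For a list the direction is that of limma's camera, against all other genes, and the value printed is the list's median. The matrix and adhesion median between the GFP- classes lay below 0 but above the median of all genes (-0.18). For GFP+ against GFP- endothelial cells it turned the proliferation list (0.072 and 0.077), the respiratory chain list (0.039 and 0.045), the ribosome list (0.012 and 0.018), Cdh5 (0.10 and 0.11), Gp1ba (-0.20 and -0.20), Hlf (-0.38 and -0.39), Ifi204 (-0.075 and -0.078), Ifi44 (-0.49 and -0.50), Ikzf2 (-0.23 and -0.23), Il1b (-0.66 and -0.67) and Pde3a (-0.073 and -0.076). For GFP- hematopoietic cluster cells against GFP- endothelial cells it turned the endothelial list (0.080 and 0.086), the interferon response list (-0.38 and -0.38), the matrix and adhesion list (-0.031 and -0.026), the respiratory chain list (0.094 and 0.10), the ribosome list (0.24 and 0.25), B2m (0.039 and 0.044), Dll1 (-0.10 and -0.10), Lcp1 (0.047 and 0.052), Selp (-0.85 and -0.85) and Tespa1 (-0.0055 and -0.0079). For the interaction it turned the proliferation list (-0.16 and -0.17), the respiratory chain list (-0.12 and -0.12) and the ribosome list (-0.068 and -0.074). Quantile normalization turned Cdh5 (0.0021) and the ribosome list (0.011) in endothelial cells by GFP and the respiratory chain list (0.021) in cluster cells by GFP, and the authors' table turned these lists as well (0.0020 and 0.024). The mean of probes turned Notch1 in endothelial cells by GFP (0.15), between the GFP+ classes (-0.31) and in the interaction (-0.25), where its probes have opposite signs. The cause of the turns under quantile normalization and the authors' table was not tested. Signal over background limits genes that are dim in a group, which is why those are given as bounds.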

Other observations

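No test in this part was chosen only after its result was seen. In GFP+ cluster cells 20 of 54 proliferation genes fell, such as Rrm2 (-0.42) and Mki67 (-0.37), 0 rose and 34 did not pass. Their median was -0.15 (adjusted p = 0.00856, but adjusted p = 0.074 with an estimated correlation; 22 adjusted over the list alone). Wnt pathway genes fell in 18 of 29 cases, among them Lef1 (-1.17) and Sfrp1 (-1.15), rose in 1, Sfrp2 (0.77), and did not pass in 10. Their median was -0.32 (adjusted p = 0.00069, but adjusted p = 0.123 with an estimated correlation; 20 adjusted over the list alone). Venous and lymphatic genes fell in 9 of 13 cases, such as Tbx1 (-1.62), rose in 1, Maf (0.68), and did not pass in 3. Their median was -0.81 (adjusted p = 0.0247, but adjusted p = 0.125 with an estimated correlation and adjusted p = 0.0503 with the slide as a block; 12 adjusted over the list alone). Of 7 mast cell and basophil genes 3 rose, Gata2 (0.50), Hdc (0.89) and Srgn (1.62), and 4 did not pass. Their median was 0.50 (adjusted p = 0.00308, but adjusted p = 0.0925 with an estimated correlation; 4 adjusted over the list alone). Matrix and adhesion genes fell in 20, rose in 6 and did not pass in 10 of 36 cases. Their median was -0.36 (adjusted p = 0.0247, but adjusted p = 0.106 with an estimated correlation; 30 adjusted over the list alone). Respiratory chain genes fell in 3 of 33 cases, Ndufa1 (-0.34), Ndufb3 (-0.26) and Ndufb5 (-0.19, 0.065 by its other probe), with 30 not passing (median -0.12, adjusted p = 0.0489, but adjusted p = 0.613 with an estimated correlation; 0 adjusted over the list alone), and the median turned to 0.021 with quantile normalization.

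In GFP+ endothelial cells immediate early genes rose in 14, fell in 7 and did not pass in 10 of 31 cases (median relative to all genes 0.33, adjusted p = 0.0063, but adjusted p = 0.0814 with an estimated correlation; 21 adjusted over the list alone), with Klf4 (1.23) higher. Cytokine receptors rose in 11, fell in 7 and did not pass in 10 of 28 cases (relative median 0.20, adjusted p = 0.00856, but adjusted p = 0.0882 with an estimated correlation; 18 adjusted over the list alone), with the oncostatin M receptor gene Osmr (1.61) higher. Matrix and adhesion genes rose in 12, fell in 9 and did not pass in 15 of 36 cases. Their relative median was 0.18 (adjusted p = 0.0199, but adjusted p = 0.102 with an estimated correlation; 21 adjusted over the list alone). Between the GFP- groups, genes of epithelium, germ cells and neurons fell in 9 of 22 cases in cluster cells, such as Stmn2 (-0.91), and 13 did not pass. Their median was -0.24 (adjusted p = 0.00228, but adjusted p = 0.115 with an estimated correlation; 10 adjusted over the list alone). The glycolysis, lymphoid, cell cycle inhibitor and interferon signalling lists passed in none of the 5 contrasts by limma's camera, at the preset or the estimated correlation; in hematopoietic cluster cells their GFP contrasts had medians of -0.21, 0.067, -0.068 and 0.046.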
